A study of Homo sapiens with 12 samples.

How the data were processed

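RNA was sequenced in 12 libraries of HCT116 cells in 3 groups of 4, taken from the sample titles and treatment labels: 0 h, DMSO recovery and UNC0642 recovery. File names were not used for grouping, and those of the UNC0642 group do not mention the inhibitor. Total RNA was extracted with Trizol and libraries were made by a service company, per the labels' protocols. Reads were processed with RSEM 1.2.4 and Bowtie against hg18, per the submitters' processing notes. The role of each tool beyond this, the strandedness of the kit and the strand used in counting are not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as ribosomal protein, keratin, histone, ferritin and zinc-finger genes, are uncertain. The deposited files give, per gene, expected counts (RSEM estimates that need not be whole), FPKM, lengths and effective lengths, per the file headers. The deposited TPM values were not used here. Between 53.3% and 57.6% of the expected counts above 0 were whole (within 0.005) in each library.

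Expected counts were rounded to whole numbers. Totals per library were 14658082 to 20179847 and 14335 to 14887 genes had a count, and the 10 most abundant genes took 5.18% to 5.42% of the counts. Within groups the pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 2.04 to 3.56 over 18 pairs), so none was counted as a duplicate, and the correlation of log2 CPM was 0.991 to 0.994. Genes were filtered with filterByExpr, which kept 12741 of 18969, and tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors) in R 4.3.3, with all 12 libraries in 1 fit and a mean per group. Mean TMM factors were 0.974 at 0 h, 1.011 after DMSO recovery and 1.015 after UNC0642 recovery. Tests are two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p of genes in the text come from this test unless another is named. Log2 fold changes are given with standard errors from the fit, and CPM with SD over 4 libraries.

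Lists of genes (31, of which 30 had the 5 tested members required) were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation 10, 11 and 7 lists were called, where 17, 17 and 16 were with the preset one. The fry test was run beside camera and asks only whether a list's genes move, on balance, one way, without comparing them with other genes. Counts adjusted over the list alone use Benjamini-Hochberg over the members. Named genes were chosen by a rule that was also fixed then. It takes, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, leaving out small and unnamed RNA genes. It adds up to 4 members of each list with the smallest p, and always EHMT1, EHMT2, MAT2A and ASNS. Some genes that the rule names are not reported here. The text gives part of the list members so chosen.

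Settings fixed beforehand as alternatives were RLE factors, library totals only, no filter and a stricter filter (CPM of at least 1 in at least 4 libraries). Others were offsets from effective lengths, unrounded counts, replicate number as a block, only the 8 libraries compared, each library left out in turn, limma-voom, DESeq2 1.42.0, and log2 FPKM with a pseudocount of 1 in limma. Alternatives added after the data were seen were length-gap class as a covariate, each class alone, leaving out 6 libraries with COL1A2 above 1 CPM, a correction for gene length and GC content, counts thinned to the smallest total, and a split of the DMSO libraries. No scaling moved the median of all genes by over 0.1. A RefSeq gene table (assembly GRCh38) was used only for names and gene order: 98.8% of genes had a place in it, and 98.5% had a GC content from GENCODE transcripts of the same assembly. Comparisons that share libraries were set beside 20 simulated draws of unchanged groups and beside fits with the shared libraries split.

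The tests were tried on simulated counts for UNC0642 against DMSO recovery with 12741 genes, of which 12675 were tested. Of 50 genes changed per fold, 72% were recovered at 1.2-fold, 84% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. False calls made up 7.28% of calls (15 genes), above the 5% aimed at, and 2 genes were called in a comparison without change.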

Results

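RNA was measured by sequencing in HCT116, an established human colorectal carcinoma cell line, in 12 libraries that form 3 groups of 4. In the recovery groups, cells had spent 24 h in medium free of methionine, with UNC0642 or with its vehicle DMSO, and then 24 h in medium containing methionine and no inhibitor. UNC0642 inhibits EHMT1 and EHMT2 (GLP and G9a), the methyltransferases that place mono- and dimethyl marks on lysine 9 of histone H3. The remaining group is labelled 0 h, and the labels leave open whether it was collected before the restriction or at its end. The deposited expected counts summed to 14658082 to 18246690 per library at 0 h, 16181056 to 20179847 after DMSO recovery and 17882236 to 19939398 after UNC0642 recovery. Of 18969 genes listed, 12741 had enough counts to be tested, and the biological coefficient of variation was 3.44%. No label says whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

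The first principal component of log2 CPM held 36.9% of the variance and placed the 0 h libraries apart from both recovery groups. The second held 10.2% and placed the DMSO libraries apart from the UNC0642 libraries. The libraries also fell into classes by the gap between gene length and effective length, which may reflect fragment or read length. Of the libraries, 5 had a gap of 101 to 106 bases and 7 a gap of 120 to 127 bases. Each group held libraries of both classes.

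**Figure D1:**
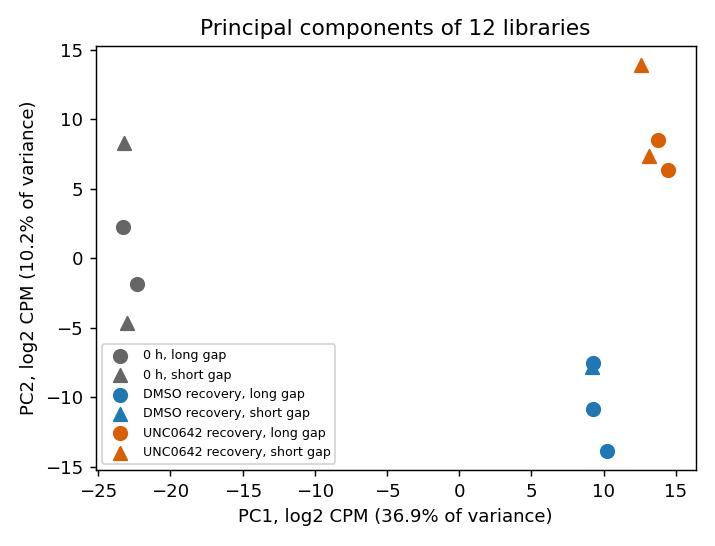
Principal component scores of the 12 libraries from log2 CPM, with the first component (36.9% of variance) on the horizontal and the second (10.2%) on the vertical axis, coloured by group and marked by length-gap class. The 3 groups occupy separate areas, and circles and triangles mix within them.

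The comparison of DMSO recovery with 0 h asks how transcripts of the recovered cells differ from those at 0 h. The largest changes are given here among called genes with a mean log2 CPM of at least 1 and no overlap of the groups. KRT81, a hair keratin, was 11.8-fold higher after recovery (log2 fold change 3.56 ± 0.17, SE, n = 4 per group), at 10.0 ± 1.47 CPM (SD) against 0.831 ± 0.234 CPM. The linker histone gene HIST1H1C rose 4.74-fold and the actin-bundling LCP1 4.54-fold, followed by the lipase gene LIPG (3.56-fold), KRT7 (3.53-fold), SYNPO (3.45-fold), CCDC80 (3.17-fold), the efflux transporter gene ABCC3 (3.03-fold), MYO7A (2.95-fold) and MAP2 (2.86-fold). The largest falls within this limit were smaller: TNNC1, a troponin, was 2.10-fold lower, SLC16A6 1.84-fold, OR51B5 1.77-fold, the glucose transporter gene SLC2A3 1.71-fold, OGDHL 1.66-fold, CYR61 1.64-fold, GMEB1 1.58-fold, NUAK2 1.57-fold and C3orf78 1.55-fold. By that limit on the choice, each of these genes was higher or lower in 4 of 4 libraries, without overlap between the groups. KRT81 resembles other hair keratins closely enough to share reads with them, so its level is uncertain.

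Cholesterol and fatty acid synthesis genes, p53 targets, interferon-stimulated genes and NRF2 targets were higher as lists after DMSO recovery. Of 25 measured cholesterol synthesis genes, 22 rose, 1 fell and 2 were not called, with a median log2 fold change of 0.49. The sterol sensor gene INSIG1 changed by 1.07 ± 0.05 and HMGCS1, an early enzyme of the pathway, by 0.74 ± 0.04. Of 15 fatty acid synthesis genes, 14 rose and 1 fell, among them the desaturase gene SCD (0.77 ± 0.02) and FASN (0.54 ± 0.03). Among p53 targets 14 of 26 rose and 4 fell, led by the cell cycle inhibitor CDKN1A (0.95 ± 0.03) and GDF15 (0.72 ± 0.06). Of 29 interferon-stimulated genes, 17 rose, including DTX3L (0.77 ± 0.06) and OAS3 (0.43 ± 0.04), while the ubiquitin-like ISG15 was the 1 that fell (-0.41 ± 0.05). Among NRF2 targets 10 of 20 rose and 4 fell, with the ferritin genes FTH1 at 0.52 ± 0.02 and FTL at 0.40 ± 0.02. The camera adjusted p was 2.05e-28 for cholesterol synthesis, 1.91e-16 for fatty acid synthesis, 5.74e-06 for p53 targets, 0.000206 for interferon-stimulated genes and 0.00182 for NRF2 targets, and each call held with an estimated correlation. Adjusted over the list alone, 18 interferon-stimulated genes rose, and the other counts in this group of lists were the same.

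Lists of ribosomal protein, ribosome biogenesis, OXPHOS and translation factor genes were lower. Of 82 cytosolic ribosomal protein genes 74 fell and 3 rose, with a median of -0.20, and RPSA changed by -0.37 ± 0.02 and RPS20 by -0.42 ± 0.03. Of 30 ribosome biogenesis genes 28 fell, including the nucleolar NOP56 (-0.35 ± 0.03) and RRS1 (-0.44 ± 0.04). Of 39 genes of mitochondrial biogenesis and oxidative phosphorylation (OXPHOS), 30 fell and 9 were not called, with NDUFB8 at -0.45 ± 0.04. Among translation factors 11 of 18 fell and 3 rose, with EIF4A1 at -0.24 ± 0.02. The camera adjusted p was 1.79e-28 for ribosomal proteins, 2.10e-14 for ribosome biogenesis, 3.14e-10 for OXPHOS and 0.000478 for translation factors. With an estimated correlation the ribosomal protein call was lost (adjusted p = 0.107) and so was the OXPHOS call (adjusted p = 0.0952). Adjusted over the list alone, 76 ribosomal protein genes and 31 OXPHOS genes fell. Log2 fold changes across genes correlated with gene length (Spearman 0.21), and correcting for length and GC content lowered the falls among ribosomal proteins to 58 and among OXPHOS genes to 23.

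The immediate early, unfolded protein response and amino acid response lists were lower after DMSO recovery. In the immediate early list 17 of 22 fell and 1 rose, with DUSP5 at -0.50 ± 0.03, MYC at -0.30 ± 0.02 and EGR1 at -0.63 ± 0.06 (adjusted p = 4.44e-08). In the unfolded protein response list 13 of 20 fell and 1 rose, led by the chaperone gene HSP90B1 at -0.45 ± 0.02 (adjusted p = 1.68e-06). In the amino acid response list 18 of 31 fell and 5 rose, including the transcription factor gene ATF4 (-0.28 ± 0.02) and the transporter gene SLC7A5 (-0.21 ± 0.02), with adjusted p = 0.000816. Hypoxia and glycolysis genes were lower, with 4 up and 11 down of 26, LDHA at -0.24 ± 0.02 and adjusted p = 0.00965 (adjusted p = 0.208 with an estimated correlation). Serine and folate one-carbon genes were lower, with 1 up and 9 down of 18, MTHFD2 at -0.22 ± 0.03 and adjusted p = 0.0288 (adjusted p = 0.145 with an estimated correlation). Mesenchymal genes were lower, with 2 up and 6 down of 16, TAGLN at -0.61 ± 0.14 and adjusted p = 0.0399 (adjusted p = 0.0952 with an estimated correlation). Neuronal genes were higher, with 8 up and 2 down of 12, VGF at 0.88 ± 0.04 and adjusted p = 0.0179 (adjusted p = 0.111 with an estimated correlation). Intestinal differentiation genes were higher, with 6 up and 1 down of 12, KRT8 at 0.20 ± 0.02 and adjusted p = 0.0155 (adjusted p = 0.111 with an estimated correlation). With counts adjusted over the list alone, 5 hypoxia genes rose and 13 fell. The same counts were 2 and 10 for serine and folate, 3 and 6 for mesenchymal genes, and as above for the others. The mesenchymal call was also lost without 0 h 3 or DMSO 2 (adjusted p = 0.0555 to 0.0797, and 0.0112 to 0.170 over all its alternatives). It was lost too with a stricter filter, with correction for length and GC content (adjusted p = 0.0810, range 0.0112 to 0.170) and without 6 libraries with traces of COL1A2. Library totals alone (adjusted p = 0.0508, range 0.0112 to 0.158), the correction and leaving out the 6 libraries each ended the serine and folate call. The neuronal call ended without the 6 libraries (adjusted p = 0.0827, range 0.0103 to 0.111) and with the correction.

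The other lists did not pass the test for DMSO recovery against 0 h. In the methionine cycle list 6 of 20 rose and 5 fell, including the polyamine enzyme gene ODC1 (-0.38 ± 0.02) and AHCY (-0.28 ± 0.03), with adjusted p = 0.205. Its median was -0.02, its mean 0.06 and its test direction down, and the median was 0.04 with libraries scaled by totals alone. The H3K9 methylation machinery had 2 up and 7 down of 19, with the corepressor gene TRIM28 at -0.13 ± 0.02 (adjusted p = 0.187). The H3K9 demethylases had 2 up and 2 down of 11, with PHF8 at -0.30 ± 0.06 (adjusted p = 0.640). Other methyltransferases had 4 up and 10 down of 31, with PRMT1 at -0.28 ± 0.03 (adjusted p = 0.205, median -0.02 and 0.03 with totals alone). Heat shock genes had 4 up and 9 down of 18 (adjusted p = 0.205), and in the mitosis list 11 of 31 fell and 20 were not called (adjusted p = 0.0850). WNT targets had 6 up and 4 down of 16 (adjusted p = 0.424). DNA replication genes had 6 up and 10 down of 34 (adjusted p = 0.463, median -0.03 and 0.03 with totals alone, where 10 rose and 5 fell). NF-kB genes had 3 up and 4 down of 15 (adjusted p = 0.616), a median of 0.08 and a mean of 0.10, but a test direction of down. Autophagy genes had 7 up and 6 down of 27 (adjusted p = 0.686), with a median of -0.04, a mean of 0.03, a test direction of up and a median of 0.02 with totals alone. Replication-dependent histones had 3 up and 2 down of 8 (adjusted p = 0.0761), with a median of -0.01, a mean of 0.01, a test direction of up and a median of 0.04 with totals alone. Zinc-finger genes named ZNF had 33 up and 49 down of 392, with ZNF469 at 0.70 ± 0.08 (adjusted p = 0.510) and a median of -0.03. With totals alone the median of this list was 0.02, and 59 rose and 26 fell. Of germline genes only 3 were measured, too few to test, and MAGEB2 fell (-0.09 ± 0.03). Adjusted over the list alone, 7 methionine cycle genes rose and 9 fell, 22 zinc-finger genes rose and 37 fell, and the other counts were the same. Mitosis genes passed without DMSO 4 (adjusted p = 0.0414, and 0.0358 to 0.320 over all its alternatives), and also when low-count genes were kept. Correction for length and GC content brought past the threshold the lower H3K9 methylation machinery (adjusted p = 0.0245, range 0.0245 to 0.320) and other methyltransferases (0.0134, range 0.0134 to 0.398). It did the same for the higher histones (0.0203, range 0.0203 to 0.896), which also passed with a stricter filter.

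In all, edgeR called 5617 of 12741 genes for DMSO recovery against 0 h, of which 2851 rose and 2766 fell, and 552 rose and 76 fell by over 1.5-fold. Groups did not overlap in 38.3% of genes, against 2.86% by chance. With libraries scaled by totals alone 67.5% of calls were rises, 68.5% with log2 FPKM and 41.2% with correction for length and GC content, against 50.8% here. Within the long-gap libraries (3 against 2) 4569 genes were called, and within the short-gap libraries (1 against 2) 2702. Both come from 1 fit of all libraries, in which the lone short-gap DMSO library is assumed to vary like the others. Markers of blood, fibroblasts and endothelium did not pass as a list (adjusted p = 0.325), though 2 of 10 rose and 6 fell. Among them were HBA1 at -1.36 ± 0.32, HBB at -1.72 ± 0.45, COL1A2 at -2.49 ± 0.81 and HBA2 at -1.68 ± 0.57, each with a 0 h mean of under 3 CPM. COL1A2 was above 1 CPM in 6 libraries (0 h 1, 2 and 3, DMSO 1, UNC0642 3 and 4). Without them, which leaves a single 0 h library, 2987 genes were called while HBB and HBA2 were higher rather than lower (log2 fold changes of 2.69 and 6.13, not called). COL1A2 was not called without 0 h 3 (adjusted p = 0.142, and 1.25e-07 to 0.541 over all its alternatives). HBA2 was not called without 0 h 1, 0 h 2 or DMSO 1 (adjusted p = 0.0648 to 0.108, and 0.000750 to 0.235 over all its alternatives). Without DMSO 2 its log2 fold change was -2.54. COL1A2 was at 1.85 CPM in DMSO 1 and at 6.81 CPM in 0 h 3, and its log2 fold change was -1.63 without 0 h 3. Without DMSO 1 the DMSO libraries held 1 count of COL1A2, which in summed counts was 150.0-fold lower than at 0 h (95% counting interval 26.6 to 5960). That interval leaves out the spread between libraries: 0 h 4 was at 0 CPM and 0 h 2 at 1.74 CPM, against 6.81 CPM in 0 h 3. The files do not tell whether these traces of blood and fibroblast genes come from the HCT116 cells, so their fold changes are values of the libraries only. COL1A2 and HBA2 were also not called with DESeq2, and neither they nor HBB with limma-voom or log2 FPKM. Within the short-gap libraries none of these 4 was called, nor were C3orf78, TNNC1, PHF8, TAGLN and MAGEB2. MYO7A and MAGEB2 were not called without the 6 libraries, and MAGEB2 was not called with totals alone, log2 FPKM or correction for length and GC content. The labels leave open whether the comparison holds the restriction with the recovery or the recovery alone, and culture time differs between these groups as well.

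The comparison of UNC0642 recovery with 0 h asks the same of cells restricted in the presence of the inhibitor. KRT81 was 23.8-fold higher (log2 fold change 4.57 ± 0.15, SE, n = 4 per group), HIST1H1C 8.76-fold, LCP1 6.84-fold and KRT7 3.96-fold. HIST2H2AA3 and HIST2H2AA4, copies that share their reads and had the same values, were 3.85-fold higher, followed by SYNPO (3.76-fold), LIPG (3.60-fold), CCDC80 (3.58-fold) and ABCC3 (3.55-fold). Under the same limit on expression and overlap, all but TNNC1 (1.93-fold lower) of the 10 largest falls were zinc-finger genes: ZNF274 was 2.34-fold lower, ZNF613 2.09-fold, ZNF416 2.07-fold, ZNF530 2.06-fold, ZNF134 2.04-fold, ZNF283 2.02-fold, ZNF567 2.02-fold, ZNF266 1.98-fold and ZNF577 1.91-fold. Zinc-finger genes resemble each other, so single values are uncertain.

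Across the zinc-finger list 164 of 392 fell, 26 rose and 202 were not called, with a median of -0.19 and adjusted p = 1.94e-05. Cholesterol synthesis genes were higher (18 up, 3 down of 25, adjusted p = 4.72e-06), with INSIG1 at 0.50 ± 0.05. Fatty acid synthesis genes were higher (11 up, 1 down of 15, adjusted p = 4.00e-07), with SCD at 0.53 ± 0.02. Among p53 targets 15 of 26 rose and 3 fell, with CDKN1A at 0.87 ± 0.03 (adjusted p = 1.94e-05). Among interferon-stimulated genes 16 of 29 rose, and ISG15 was the 1 that fell (-0.62 ± 0.05, adjusted p = 0.000376). Among NRF2 targets 9 of 20 rose and 5 fell, with FTH1 at 0.63 ± 0.02 and the efflux transporter gene ABCC2 at 1.03 ± 0.05 (adjusted p = 0.000654). Among neuronal genes 9 of 12 rose and 1 fell, with VGF 2.30-fold higher (adjusted p = 9.26e-05). Replication-dependent histones had 3 up and 3 down of 8, with HIST1H2BD at 1.33 ± 0.19 and HIST1H4A 4.00-fold lower. HIST1H4A was at only 0.788 to 0.982 CPM at 0 h, so its fold rests on few counts. The histone list's adjusted p = 0.00169 in the upward direction was lost when low-count genes were kept (adjusted p = 0.820, range 0.000160 to 0.820). Intestinal differentiation genes were higher (8 up, 1 down of 12, EPCAM -0.18 ± 0.02), with adjusted p = 0.0144, a call lost with an estimated correlation (adjusted p = 0.107). Taking the counts adjusted over the list alone, 10 NRF2 targets rose, and the other counts of these lists were the same.

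Ribosomal protein genes fell in 78 of 82 cases (median -0.25, adjusted p = 2.07e-39), with RPS21 at -0.52 ± 0.03, a list call lost with an estimated correlation (adjusted p = 0.0587). Ribosome biogenesis genes fell in 27 of 30 cases (NPM1 -0.22 ± 0.02, adjusted p = 1.93e-11). OXPHOS genes fell in 30 of 39 cases (ATP5F1 -0.38 ± 0.03, adjusted p = 3.86e-11), and this call was lost too (adjusted p = 0.0699 with an estimated correlation). Translation factors fell in 13 of 18 cases (EEF1B2 -0.33 ± 0.03, adjusted p = 7.50e-05) and unfolded protein response genes in 13 of 20 (HSP90B1 -0.50 ± 0.02, adjusted p = 7.29e-06). After correction for length and GC content 69 ribosomal protein and 25 OXPHOS genes fell. The H3K9 methylation machinery was lower (1 up, 8 down of 19, CBX3 -0.17 ± 0.02), with adjusted p = 0.0365 (adjusted p = 0.0699 with an estimated correlation). Heat shock genes were lower (2 up, 11 down of 18, HSPD1 -0.23 ± 0.02), with adjusted p = 0.0365 (adjusted p = 0.187 with an estimated correlation). Serine and folate genes were lower (1 up, 11 down of 18, SHMT2 -0.19 ± 0.03), with adjusted p = 0.0365 (adjusted p = 0.163 with an estimated correlation). The H3K9 methylation call was also lost without 0 h 3 (adjusted p = 0.0582, and 0.00409 to 0.0916 over all its alternatives). The heat shock call was lost without UNC0642 2 (adjusted p = 0.0525, and 0.00677 to 0.246 over all its alternatives). The serine and folate call was lost without 0 h 2 (adjusted p = 0.0530, and 0.0139 to 0.229 over all its alternatives). Without the 6 libraries the H3K9 methylation and serine calls were lost too, and the serine call with correction for length and GC content. Library totals alone ended all 3 of these calls (adjusted p = 0.0916, 0.246 and 0.0744 in the same order). Falls adjusted over the list alone numbered 79 for ribosomal proteins, 28 for ribosome biogenesis, 31 for OXPHOS and 14 for translation factors. They numbered 9 for H3K9 methylation, 12 for heat shock and 13 for the unfolded protein response, and 2 serine and folate genes rose.

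The rest of the lists were not called for UNC0642 recovery against 0 h. The amino acid response had 8 up and 15 down of 31 (adjusted p = 0.127). Its median was -0.01, its mean 0.00 and its test direction down, and the median was 0.04 with totals alone. The methionine cycle list had 5 up and 11 down of 20, with MAT1A at 2.73 ± 0.29 (adjusted p = 0.129, median -0.09, mean 0.09, test direction down). Hypoxia and glycolysis had 8 up and 10 down of 26 (adjusted p = 0.258), with a median of -0.03, a mean of 0.03 and a test direction of down. With totals alone the median was 0.03, and 11 rose and 9 fell. In the immediate early list 6 rose and 9 fell of 22, with EGR1 at 0.60 ± 0.06 and DUSP5 at -0.39 ± 0.03 (adjusted p = 0.349). H3K9 demethylases had 1 up and 4 down of 11 (adjusted p = 0.197). Other methyltransferases had 5 up and 9 down of 31 (adjusted p = 0.187, median -0.04 and 0.02 with totals alone, where 5 rose and 4 fell). DNA replication genes had 4 up and 12 down of 34 (adjusted p = 0.0615, median -0.03 and 0.03 with totals alone). Mitosis genes had 3 up and 6 down of 31 (adjusted p = 0.607, median -0.00 and 0.06 with totals alone, where 13 rose and 3 fell). NF-kB genes had 3 up and 3 down of 15 (adjusted p = 0.504), and autophagy genes 6 and 5 of 27 (adjusted p = 0.828). WNT targets had 6 up and 2 down of 16 (adjusted p = 0.0596), and mesenchymal genes 1 and 4 of 16 (adjusted p = 0.380). Markers of other cell types had 2 up and 2 down of 10 (adjusted p = 0.691). Of the germline genes MAGEB2 fell (-0.07 ± 0.03), a call lost without 0 h 1, 0 h 2, 0 h 4, UNC0642 1 or UNC0642 4 (adjusted p = 0.0505 to 0.140, and 0.0179 to 0.787 over all its alternatives). That call was also lost within either length-gap class, without the 6 libraries, and with totals alone, low-count genes kept, log2 FPKM or the correction for length and GC content. WNT targets were called without 0 h 2, 0 h 4 or UNC0642 2 (adjusted p = 0.0430 to 0.0458, and 0.0330 to 0.229 over all its alternatives), and with totals alone. DNA replication genes were called without 0 h 4 or UNC0642 3 (adjusted p = 0.0437 to 0.0484, and 0.0233 to 0.249 over all its alternatives), and with low-count genes kept. After correction for length and GC content the amino acid response (adjusted p = 0.0142, range 0.0142 to 0.249) and H3K9 demethylases (0.0351, range 0.0351 to 0.273) passed in the downward direction. Other methyltransferases did too (adjusted p = 0.00634, range 0.00634 to 0.377). Adjusted over the list alone, 9 amino acid response genes rose, no germline gene was called (1 of 3 had an unadjusted p under 0.05 in edgeR), and the other counts were the same.

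edgeR called 5990 genes for UNC0642 recovery against 0 h, of which 2983 rose and 3007 fell, and 630 rose and 118 fell by over 1.5-fold. Groups did not overlap in 40.2% of genes, against 2.86% by chance. With totals alone 67.5% of calls were rises with log2 FPKM 67.3% and with correction for length and GC content 42.7%, against 49.8% here. Within the long-gap libraries (2 against 2) 4392 genes were called and within the short-gap libraries (2 against 2) 4037. HBB (-1.79 ± 0.46) and HBA1 (-1.02 ± 0.30) were lower than at 0 h, and without the 6 libraries with COL1A2 above 1 CPM 2836 genes were called while HBB had a log2 fold change of 1.92 (not called). ZNF577, ZNF613 and HBA1 were not called without these libraries. HBA1 was not called in the long-gap libraries, and HBB was not called in the short-gap libraries or with limma-voom or log2 FPKM.

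Both recoveries differed from 0 h in many of the same genes, since 4541 genes were called in the same direction (2261 up and 2280 down) and 20 in opposite directions. Independent lists of these sizes would share 667 genes up and 653 down, and simulated groups without change shared 0.250 genes on average over 20 draws. Both comparisons use the same 0 h libraries. When these were split between the comparisons, a mean of 3175 genes (3127 to 3207 over 6 assignments) were called in the same direction. Log2 fold changes correlated across genes with r = 0.81, against 0.53 in the simulation and a mean of 0.55 with split controls, and genes are not independent replicates. The covariance was 0.0912, against 0.00884 in the simulation and 0.0767 with split controls.

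**Figure D2:**
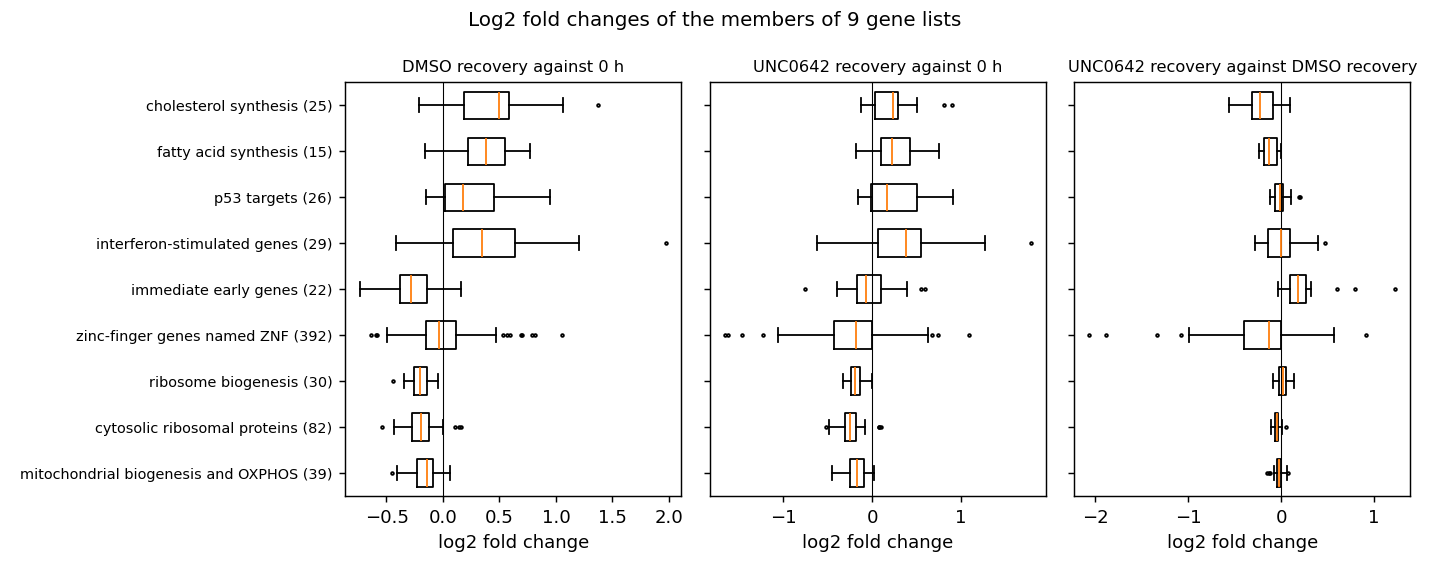
Log2 fold changes of the tested members of 9 gene lists (number of genes in parentheses) in the 3 comparisons; boxes span the quartiles with the median as a line, whiskers reach 1.5 times the box and circles are genes beyond. The medians of cholesterol synthesis genes lie above 0 against 0 h (0.49 and 0.23) and below 0 for UNC0642 against DMSO recovery (-0.22).

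The comparison of UNC0642 with DMSO recovery asks what the inhibitor, present only during restriction, left behind after 24 h without it. The names of the UNC0642 group's files mention neither the inhibitor nor its vehicle, so its identity rests on the labels. The early-response transcription factor gene EGR1 was 2.35-fold higher (log2 fold change 1.23 ± 0.06, SE, n = 4 per group), at 76.6 ± 4.97 CPM (SD) against 32.6 ± 3.18 CPM. The other largest rises, under the same limit, were JMJD7-PLA2G4B (10.7-fold), ARHGDIB (2.27-fold), FABP6 (2.22-fold), FHAD1 (2.15-fold), KRT81 (2.02-fold), COL17A1 (1.90-fold), the growth factor gene NRG1 (1.88-fold), KRT23 (1.86-fold) and HIST1H1C (1.85-fold). Of the 10 largest falls under it all but DHRS2 (1.84-fold lower) and MFSD4 (1.81-fold) were zinc-finger genes: ZNF530 (1.98-fold), ZNF614 (1.95-fold), ZNF266 (1.91-fold), ZNF567 (1.90-fold), ZNF493 (1.88-fold), ZNF274 (1.88-fold), ZNF91 (1.81-fold) and ZNF134 (1.80-fold). JMJD7-PLA2G4B had 1.24 CPM in DMSO 3 and 0 in the other 3 DMSO libraries, so its fold rests on DMSO 3. With that library left out, a floor of 3 counts over the 3 libraries at 0 gave a fold of 60.8. This is no lower bound for the whole group, where the fold was 10.7. JMJD7-PLA2G4B also stood high in UNC0642 3 (5.87 CPM, others 2.09 to 2.67). It is a readthrough of neighbouring genes that shares their reads, and it was not called with DESeq2 (adjusted p = 0.370) or log2 FPKM (0.0613), over a range of 1.02e-13 to 0.370 in the alternatives. The COL17A1 call was lost without DMSO 1 or UNC0642 2 (adjusted p = 0.0506 to 0.0592, and 0.00142 to 0.145 over all its alternatives). The ZNF493 call was lost without DMSO 1 (adjusted p = 0.0582, and 0.00542 to 0.192 over all its alternatives). The MFSD4 call was lost without DMSO 1, DMSO 3, UNC0642 1 or UNC0642 4 (adjusted p = 0.0900 to 0.127, and 0.00994 to 0.594 over all its alternatives). ZNF493 and MFSD4 were also not called in the long-gap libraries or with log2 FPKM, and ZNF493 not with effective length offsets. Within the short-gap libraries (2 against 1) FABP6, FHAD1, ZNF493, ZNF530, ZNF567 and ZNF91 were not called.

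Zinc-finger genes were lower as a group, with 96 of 392 fallen, 1 risen and 295 not called, a median of -0.13 and 75.8% of values below 0 (adjusted p = 1.33e-19). ZNF480 changed by -0.76 ± 0.06, from 29.1 ± 1.19 to 17.2 ± 0.423 CPM, ZNF320 by -0.74 ± 0.08, ZNF83 by -0.59 ± 0.06 and ZNF28 by -0.73 ± 0.08. Cholesterol synthesis genes were also lower, with 15 of 25 fallen and 10 not called (median -0.22, adjusted p = 1.59e-42), including INSIG1 (-0.56 ± 0.04), HMGCS1 (-0.45 ± 0.04) and the squalene synthase gene FDFT1 (-0.40 ± 0.04). Of 15 fatty acid synthesis genes 7 fell, with SCD at -0.24 ± 0.02 and FASN at -0.19 ± 0.03 (adjusted p = 3.22e-09). The immediate early list was higher, with 10 of 22 risen and 12 not called (adjusted p = 2.17e-24), including JUN (0.60 ± 0.06), the phosphatase gene DUSP6 (0.32 ± 0.04) and FOS (0.79 ± 0.13). Among amino acid response genes 3 of 31 rose and 1 fell, with SLC7A5 at 0.10 ± 0.02 and the stanniocalcin gene STC2 at 0.17 ± 0.04 (adjusted p = 0.000208). Among neuronal genes 2 of 12 rose, VGF (0.33 ± 0.04) and SCG2 (0.52 ± 0.11), with adjusted p = 0.000208. The replication-dependent histone list was higher (adjusted p = 0.000258), though only HIST1H1C of 8 rose and the call was lost when low-count genes were kept (adjusted p = 0.274, range 6.23e-05 to 0.274). All of these list calls held with an estimated correlation. Adjusted over the list alone, 126 zinc-finger genes fell and 5 rose, and 19 cholesterol and 8 fatty acid genes fell. In the same way 15 immediate early, 7 amino acid response, 3 neuronal and 2 histone genes rose.

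**Figure D3:**
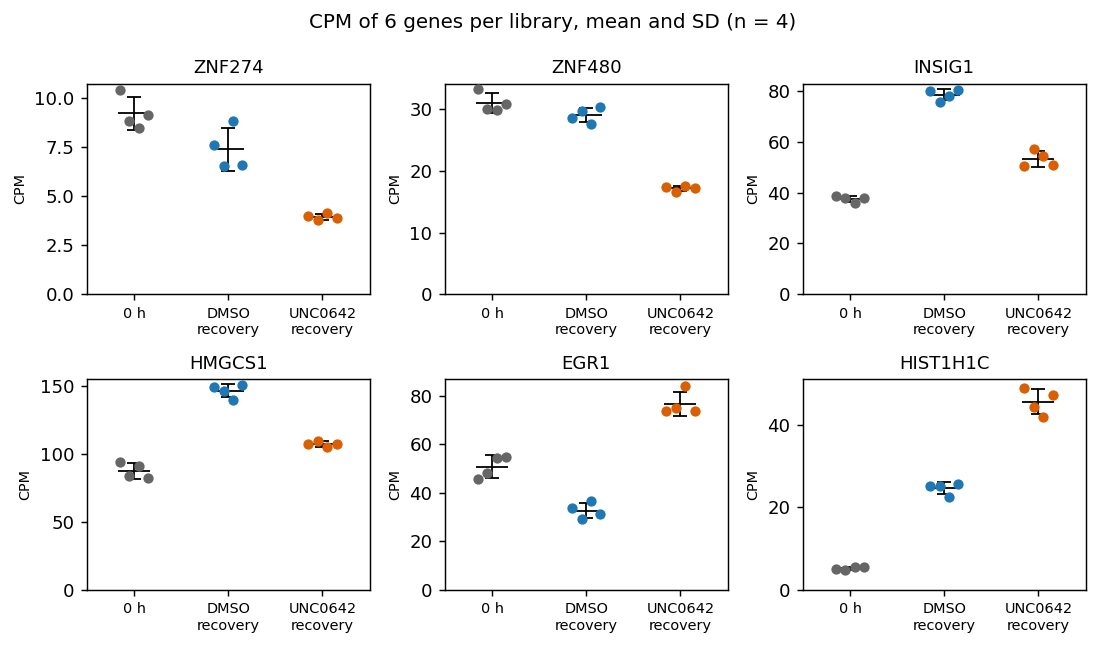
CPM of ZNF274, ZNF480, INSIG1, HMGCS1, EGR1 and HIST1H1C in each library by group, with the mean and SD of 4 libraries as bars. INSIG1 and HMGCS1 lie highest after DMSO recovery, ZNF274 and ZNF480 lowest after UNC0642 recovery, and EGR1 and HIST1H1C highest after UNC0642 recovery.

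A further set of lists passed the test only with the preset correlation. NF-kB genes were higher (3 up of 15), with IER3 at 0.27 ± 0.03, the chemokine gene IL8 at 1.88 ± 0.35 and adjusted p = 0.00642 (adjusted p = 0.106 with an estimated correlation). Hypoxia and glycolysis genes were higher (4 up of 26), with NDRG1 at 0.24 ± 0.05, SLC2A3 at 0.27 ± 0.06 and adjusted p = 0.00181 (adjusted p = 0.161 with an estimated correlation). WNT targets were higher (2 up of 16), with the WNT antagonist gene DKK1 at 0.42 ± 0.03, CCND1 at 0.07 ± 0.02 and adjusted p = 0.00923 (adjusted p = 0.143 with an estimated correlation). Mesenchymal genes were higher (3 up of 16), with CYR61 at 0.29 ± 0.05 and adjusted p = 0.00957 (adjusted p = 0.0518 with an estimated correlation). Mitosis genes were higher (1 up of 31, the kinase gene PLK1 at 0.10 ± 0.03), with adjusted p = 0.00737 (adjusted p = 0.137 with an estimated correlation). Ribosomal protein genes were lower (5 down of 82), with RPS21 at -0.10 ± 0.03, RPL14 at -0.07 ± 0.02 and adjusted p = 9.13e-09 (adjusted p = 0.398 with an estimated correlation). DNA replication genes were lower (3 down of 34), with UNG at -0.11 ± 0.03, MCM4 at -0.09 ± 0.02 and adjusted p = 0.00714 (adjusted p = 0.137 with an estimated correlation). Heat shock genes were lower (3 down of 18), with HSP90AA1 at -0.11 ± 0.02 and adjusted p = 0.0345 (adjusted p = 0.228 with an estimated correlation). H3K9 demethylases were lower (2 down of 11), with KDM3A at -0.35 ± 0.06, KDM3B at -0.12 ± 0.03 and adjusted p = 0.0415 (adjusted p = 0.137 with an estimated correlation). Counts adjusted over the list alone that differed were 27 ribosomal protein, 5 heat shock, 3 demethylase and 2 hypoxia genes down. For rises they were 1 heat shock, 6 hypoxia and 2 mitosis genes.

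Several of these calls were lost when 1 library was left out. The heat shock list was not called without DMSO 1, DMSO 4, UNC0642 2 or UNC0642 3 (adjusted p = 0.0527 to 0.127, and 0.00473 to 0.228 over all its alternatives). The H3K9 demethylase list was not called without DMSO 4, UNC0642 1, UNC0642 2 or UNC0642 3 (adjusted p = 0.0612 to 0.0736, and 0.0225 to 0.137 over all its alternatives). RPS21 was not called without DMSO 1, DMSO 2, UNC0642 2 or UNC0642 3 (adjusted p = 0.0511 to 0.0963, and 0.00334 to 0.211 over all its alternatives). RPL14 was not called without DMSO 1, DMSO 3, DMSO 4, UNC0642 1 or UNC0642 4 (adjusted p = 0.0504 to 0.0688, and 0.00747 to 0.260 over all its alternatives). UNG was not called without DMSO 4 or UNC0642 2 (adjusted p = 0.0521 to 0.0820, and 0.000895 to 0.438 over all its alternatives). MCM4 was not called without DMSO 2, DMSO 3, DMSO 4, UNC0642 1, UNC0642 2 or UNC0642 4 (adjusted p = 0.0541 to 0.163, and 0.00553 to 0.740 over all its alternatives). KDM3B was not called without DMSO 3, DMSO 4 or UNC0642 1 (adjusted p = 0.0516 to 0.0815, and 0.00339 to 0.518 over all its alternatives). CCND1 was not called without DMSO 2 or UNC0642 4 (adjusted p = 0.0541 to 0.0544, and 0.000972 to 0.264 over all its alternatives). PLK1 was not called without UNC0642 4 (adjusted p = 0.0721, and 0.00393 to 0.262 over all its alternatives). In neither length-gap class alone were UNG, MCM4, PLK1, KDM3B, SCG2, SLC2A3, CCND1, RPS21 and RPL14 called. In the short-gap libraries KDM3A, SLC7A5, STC2, IL8, NDRG1 and FOS were not called either. MCM4, KDM3B, RPS21 and RPL14 were not called with log2 FPKM, RPL14 not with correction for length and GC content, and MCM4 not with thinned counts. Heat shock genes were not called as a list with totals alone (adjusted p = 0.0543, range 0.00473 to 0.228) or without the 6 libraries, and WNT targets were not without the 6 (adjusted p = 0.0698, range 0.00558 to 0.143).

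The remaining lists did not pass for UNC0642 against DMSO recovery. In the methionine cycle list 1 of 20 rose, MAT1A (1.19 ± 0.23), with adjusted p = 0.566, a median of -0.03, a mean of 0.03 and a test direction of down. In the H3K9 methylation machinery 2 of 19 fell, ATF7IP (-0.25 ± 0.06) and the remodeller gene HELLS (-0.16 ± 0.04), with adjusted p = 0.0716. No gene was called by edgeR among 18 serine and folate genes (adjusted p = 0.999), 20 unfolded protein response genes (adjusted p = 0.999) and 39 OXPHOS genes (adjusted p = 0.154), where 0, 4 and 5 had an unadjusted p under 0.05. The same held for 10 markers of other cell types (adjusted p = 0.181) and the 3 germline genes, with 1 and 0 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0 genes in these 5 lists, and log2 FPKM called 3 OXPHOS genes as lower and 0 in the others. The medians of the serine and unfolded protein lists, both -0.00, were 0.00 with totals alone, beside means of 0.01 and 0.02 and test directions of down and up. Among p53 targets 1 of 26 rose (adjusted p = 0.999), and among interferon-stimulated genes 1 of 29 rose and 1 fell (adjusted p = 0.999). Among NRF2 targets 2 of 20 rose and 2 fell, with ABCC2 at 0.86 ± 0.05 (adjusted p = 0.349, median -0.02, mean 0.09, test direction up). Among autophagy genes 2 of 27 rose and 1 fell, with ATG12 at -0.30 ± 0.03 (adjusted p = 0.826, median 0.00, mean -0.01, test direction down). Other methyltransferases had 1 of 31 up (adjusted p = 0.866, median -0.00 and 0.00 with totals alone), and intestinal genes 1 of 12, KRT20 (1.60 ± 0.36, list adjusted p = 0.826). KRT20 was at only 0.245 to 0.731 CPM after DMSO recovery. Ribosome biogenesis genes had 1 up and 1 down of 30 (adjusted p = 0.464), and translation factors 2 down of 18 (adjusted p = 0.185). OXPHOS genes passed without DMSO 2 or UNC0642 1 (adjusted p = 0.0117 to 0.0383, and 0.0117 to 0.957 over all its alternatives), and with length-gap class as a covariate. The H3K9 methylation machinery passed without UNC0642 4 (adjusted p = 0.0405, and 0.0352 to 0.137 over all its alternatives), and with that covariate or low-count genes kept. Markers of other cell types passed without DMSO 1 (adjusted p = 0.0319, and 0.0319 to 0.673 over all its alternatives). HELLS lost its call without DMSO 2, DMSO 3, UNC0642 1 or UNC0642 3 (adjusted p = 0.0575 to 0.157, and 0.00762 to 0.621 over all its alternatives), and in either length-gap class, with log2 FPKM and with correction for length and GC content. In the short-gap libraries ATF7IP, MAT1A and KRT20 were not called, ATF7IP not with log2 FPKM and KRT20 not in the long-gap libraries. With adjustment over the list alone, 2 interferon-stimulated genes rose and 3 fell, and 3 NRF2 targets rose and 4 fell. Likewise 2 autophagy and 2 intestinal genes fell, and 1 translation factor rose and 3 fell.

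edgeR called 584 genes for UNC0642 against DMSO recovery, of which 262 rose and 322 fell, and 40 rose and 50 fell by over 1.5-fold. With totals alone 51.3% of calls were rises, against 44.9% here, so more rose than fell (303 of 591 calls). With log2 FPKM 15 rose and 7 fell by over 1.5-fold, on a scale whose pseudocount understates changes of low genes. Groups did not overlap in 10.5% of genes, against 2.86% by chance. Within the long-gap libraries (2 against 3) 271 genes were called and within the short-gap libraries (2 against 1) 125, with the lone DMSO library assumed to vary like the others. Without the 6 libraries with COL1A2 above 1 CPM, which leaves 3 DMSO and 2 UNC0642 libraries, 277 were called, not among them COL17A1, MFSD4, ZNF493, HELLS, UNG, PLK1, SCG2, CCND1, KRT20, CYR61, SLC2A3, SLC7A5, STC2, RPS21 and RPL14. Of the 584 genes, 335 were also called for DMSO recovery against 0 h, 132 in the same and 203 in the opposite direction (104 up with recovery and lower with UNC0642, 99 down with recovery and higher with UNC0642). Independent lists would give 58.6 both up, 69.9 both down, and 72.1 and 56.9 in opposite directions. The DMSO libraries enter both comparisons with opposite signs, and with them split the mean counts were 72.5 in the same and 80.2 in the opposite direction. The correlation of log2 fold changes was -0.24, against -0.48 in simulated groups without change and -0.09 with split libraries, with covariances of -0.0165, -0.00773 and -0.00811.

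The targets of the inhibitor and a pair of methionine-responsive genes were followed in every comparison. EHMT1 changed by -0.13 ± 0.04 after DMSO recovery (adjusted p = 0.00543) and by -0.13 ± 0.04 after UNC0642 recovery (adjusted p = 0.00478) against 0 h. Both calls were lost with library totals alone (adjusted p = 0.0891, range 2.18e-06 to 0.268, and 0.107, range 1.04e-06 to 0.271), with log2 FPKM, in the short-gap libraries and without the 6 libraries. EHMT2 had log2 fold changes of -0.03 ± 0.03 (adjusted p = 0.500) and -0.04 ± 0.03 (adjusted p = 0.347). It was called as lower only after correction for length and GC content (adjusted p = 0.000383, range 0.000383 to 0.932, and 4.93e-05, range 4.93e-05 to 0.773). MAT2A, the S-adenosylmethionine synthetase gene of most tissues, changed by -0.24 ± 0.02 and -0.24 ± 0.02. ASNS, an asparagine synthetase gene raised by amino acid shortage, rose after UNC0642 recovery (0.17 ± 0.04, adjusted p = 0.000938), a call lost without the 6 libraries (adjusted p = 0.0806, range 2.52e-05 to 0.0806). After DMSO recovery its value was 0.09 ± 0.04 (adjusted p = 0.0797), called without 0 h 2 or DMSO 2 (adjusted p = 0.0354 to 0.0465, and 0.00521 to 0.434 over all its alternatives), and with totals alone, log2 FPKM and the correction. Between UNC0642 and DMSO recovery edgeR, DESeq2, limma-voom and log2 FPKM called 0 of the 4 and 0 had an unadjusted p under 0.05, with edgeR's adjusted p of 0.997, 0.931, 0.946 and 0.296 for EHMT1, EHMT2, MAT2A and ASNS.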

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

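The corrections for gene length and GC content and the thinned counts were chosen only after the data were seen, and so were the extra look at zinc-finger genes with whole counts among the neighbours and the reading of the ribosomal protein test in each comparison alone.

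Zinc-finger genes were lower after UNC0642 than after DMSO recovery, with 96 of 392 fallen and a median log2 fold change of -0.13. Low expression is argued against, because none of 10000 lists of other genes matched on mean log2 CPM had a median as low. The lowest of their medians was -0.02, and p from these draws was 0.0001, the smallest they can give. Gene length and GC content are argued against as the whole cause, since the median after the correction was -0.12 (95% interval -0.15 to -0.09) and 99 of 391 genes fell. The intervals of this paragraph resample genes as if independent. Reads shared between paralogs stay open: the 118 zinc-finger genes with whole expected counts (within 0.005) in at least 11 libraries had a median of -0.16, but its interval of -0.23 to -0.06 reaches above the bound of 50% of the list's median set for the test. An effect of the inhibitor on these genes may also account for the pattern and was not tested apart from these.

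Ribosomal protein and OXPHOS genes were lower in both recoveries than at 0 h with the preset correlation, and all 4 list calls were lost with an estimated one (adjusted p = 0.107 and 0.0587 for ribosomal proteins, and adjusted p = 0.0952 and 0.0699 for OXPHOS, after DMSO and UNC0642 recovery). The choice among TMM factors, RLE factors and library totals did not make the whole fall, because the lowest share of a median kept under another scaling was 63.0%. Each of these scalings shifts all genes of a library alike and is relative to the other libraries. A change in the total RNA of the cells was therefore not addressed. With the correction for gene length and GC content the ribosomal protein median after UNC0642 recovery moved from -0.25 to -0.14 (56.8% kept). Its 95% interval of -0.16 to -0.13 stayed below the bound of 50% of the median set for the test. That interval resamples genes as if independent, while their estimated correlation was 0.53, so it is too narrow to decide. For the rest, gene length and GC content cannot be told apart from other causes: the ribosomal protein median after DMSO recovery moved from -0.20 to -0.10 (52.1% kept), and the OXPHOS medians from -0.14 to -0.09 (60.4% kept, DMSO) and from -0.17 to -0.10 (57.7% kept, UNC0642). What keeps it open is that these 3 intervals reach the bound of 50% of the median. The treatment before collection and the longer culture may each account for what remains, and the design holds no group that parts them.

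More genes rose than fell by over 1.5-fold in the recoveries, with 552 rises and 76 falls for DMSO and 630 and 118 for UNC0642. Lower depth of the 0 h libraries is argued against, because rises made up at least 84.0% of such calls in both comparisons with all libraries thinned to the smallest total. Gene length and GC content are argued against too, with rises at 82.2% or more after the correction. A change of the cells between 0 h and the end of recovery, whether or not it takes in the restriction, may account for the pattern together with culture time and was not tested further.

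Each count of called genes was set beside every split of the 8 libraries compared into groups of 4, fitted without the remaining group. The other splits mix libraries of both groups, so the group difference enters their spread and lowers their calls. The smallest share they can give is 1 of 35. They cannot tell a treatment from a difference between single cultures, so chance is not excluded by them. For DMSO recovery against 0 h the real split called 5679 genes and the highest of the others 1, so 1 of 35 splits gave as many. For UNC0642 recovery against 0 h the values were 5906 and 0, again 1 of 35. For UNC0642 against DMSO recovery they were 558 and 2, and 1 of 35.

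Single libraries stood apart from the other 3 of their group, by a gap larger than the critical share of the range, in 55 of 789 sets of values (genes named by the rule and 3 measures per library). Chance gives about 5% of such sets, 39.45 here. Values of 0 h library 1 lay above the rest for PRMT1 (501 CPM, others 466 to 469), RPSA (2107 CPM, others 2018 to 2019), ATG12 (211 CPM, others 203 to 205), HIST2H2BE (2.48 CPM, others 1.18 to 1.29) and RPL14 (957 CPM, others 918 to 921). 0 h library 3 was high for EHMT2 (135 CPM, others 125 to 126) and ZNF530 (7.16 CPM, others 5.08 to 5.19). Values of 0 h library 4 lay above the rest for MYO7A (1.26 CPM, others 0.626 to 0.731) and MANF (87.7 CPM, others 82.7 to 83.4). 0 h library 1 was low for FABP6 (0.967 CPM, others 1.75 to 1.86). Values of 0 h library 2 lay below the rest for HIST1H4A (0.788 CPM, others 0.967 to 0.982), IER3 (297 CPM, others 315 to 318) and TAGLN (5.46 CPM, others 7.13 to 7.44). 0 h library 3 was low for SLC2A3 (31.7 CPM, others 33.4 to 33.4), ELOVL5 (86.4 CPM, others 92.0 to 92.8), SQSTM1 (286 CPM, others 304 to 305), KRT8 (2439 CPM, others 2495 to 2498) and MAT2B (77.3 CPM, others 79.3 to 79.4). Values of 0 h library 4 lay below the rest for ODC1 (903 CPM, others 933 to 938), NOLC1 (710 CPM, others 755 to 760) and DCN (0 CPM, others 0.904 to 1.01). DMSO library 1 was high for NUAK2 (9.26 CPM, others 7.84 to 8.04), COL1A2 (1.85 CPM, others 0 to 0.0490), GNL3 (272 CPM, others 260 to 262) and DCN (0.476 CPM, others at 0). Values of DMSO library 2 lay above the rest for ZNF283 (5.85 CPM, others 4.82 to 4.95) and KRT20 (0.731 CPM, others 0.245 to 0.281). DMSO library 3 was high for JMJD7-PLA2G4B (1.24 CPM, others at 0). Values of DMSO library 4 lay above the rest for OAS3 (98.3 CPM, others 89.9 to 90.6) and TEX14 (2.94 CPM, others 1.63 to 1.71). DMSO library 1 was low for MLL (136 CPM, others 146 to 147). Values of DMSO library 2 lay below the rest for CBX3 (444 CPM, others 457 to 460), PHF8 (29.6 CPM, others 35.9 to 36.8), SLC3A2 (352 CPM, others 366 to 369), FTL (1051 CPM, others 1083 to 1088) and EEF1D (405 CPM, others 416 to 419). DMSO library 3 was low for HIST1H1C (22.5 CPM, others 25.2 to 25.6) and L1CAM (16.6 CPM, others 18.2 to 18.6). Values of DMSO library 4 lay below the rest for ACACA (259 CPM, others 268 to 268). UNC0642 library 1 was high for NPM1 (2205 CPM, others 2140 to 2142). Values of UNC0642 library 2 lay above the rest for HBA1 (1.15 CPM, others 0.594 to 0.660) and ZNF516 (26.8 CPM, others 24.1 to 24.5). UNC0642 library 3 was high for MAP2 (14.1 CPM, others 11.3 to 11.8), EGR1 (84.0 CPM, others 73.5 to 75.0), JMJD7-PLA2G4B (5.87 CPM, others 2.09 to 2.67) and SYN1 (0.740 CPM, others 0.594 to 0.605). Values of UNC0642 library 4 lay above the rest for PGAM1 (754 CPM, others 728 to 732), PLK1 (266 CPM, others 253 to 254) and PRC1 (236 CPM, others 225 to 226). UNC0642 library 1 was low for KDM3B (134 CPM, others 140 to 141) and KIF2C (158 CPM, others 166 to 168). Values of UNC0642 library 2 lay below the rest for PHF8 (32.3 CPM, others 35.8 to 36.3) and NCL (2007 CPM, others 2073 to 2083). UNC0642 library 4 was low for FADS1 (72.5 CPM, others 75.8 to 76.2).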

How the results depend on the processing

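The settings by length-gap class, without libraries with traces of COL1A2, with corrections for gene length and GC content, with thinned counts and with split DMSO libraries were chosen only after the data were seen, and the rest were fixed before the data were examined. Over all alternatives, values of the genes named by the rule kept direction and side of the threshold in 10152 cases, lost a call in 387, gained one in 89 and turned direction in 3, and list tests kept theirs in 1543, lost a call in 54 and gained one in 23. Of named genes called, 107 of 136 (DMSO against 0 h), 119 of 139 (UNC0642 against 0 h) and 30 of 84 (UNC0642 against DMSO) were called in every alternative. Leaving out 1 library at a time gave 5153 to 5311, 5505 to 5697 and 402 to 618 called genes, and 16 to 18, 16 to 19 and 14 to 17 called lists, in the same order. Other tests, scalings and filters gave 5325 to 5663 genes, 5677 to 6075 and 393 to 727. Similar totals held partly different genes: of 5617 calls for DMSO against 0 h, totals alone kept 4689 and log2 FPKM 4471. Of 584 calls for UNC0642 against DMSO, log2 FPKM kept 357. Correction for length and GC content gave 5850, 6148 and 777, thinned counts 5462, 5745 and 524, and length-gap class as a covariate 5654, 6109 and 614. The correction kept 4689 of 5617 calls for DMSO against 0 h and 5005 of 5990 for UNC0642 against 0 h. It called 10 and 11 of them in the other direction. With an estimated correlation 10, 11 and 7 lists were called, where 17, 17 and 16 were with the preset one. Fewer samples gave fewer calls within length-gap classes: 2702 genes for DMSO against 0 h in the short-gap libraries, and 271 (long) and 125 (short) for UNC0642 against DMSO. Without the 6 libraries with COL1A2, which leaves a lone 0 h library assumed to vary like the other groups, 2987, 2836 and 277 genes were called. In that setting HBB had log2 fold changes of 2.69 (DMSO against 0 h) and 1.92 (UNC0642 against 0 h) and HBA2 of 6.13 (DMSO against 0 h), the reverse of the values over all libraries, because the lone 0 h library was at 0.0701 CPM for HBB and 0 for HBA2. With shared libraries split, the correlation of both recoveries was 0.55 (0.81 unsplit) and the mean count of UNC0642 calls also made for DMSO recovery was 152.7 (335 unsplit), with fewer samples per fit. With replicate number as a block 5668, 5998 and 633 genes were called. Deviations of same-numbered samples correlated at -0.10 to 0.04 with 0 of 12 pairs over 0.1. These values give no sign of a shared culture or day but cannot exclude one, and the labels do not say. Depth limits genes of few counts. The filter left many of them out of the tests, but others, such as COL1A2 and JMJD7-PLA2G4B, were tested with 0 CPM in some libraries.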

Other observations

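The 8 gene lists of this part and the check of zinc-finger genes with whole counts were chosen only after the data were seen, so their tests describe these libraries and are no independent evidence.

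Keratins, laminin-332 and hemidesmosome genes, ligands of the EGF receptor family and AP-1 subunits were higher as lists after UNC0642 than after DMSO recovery. Of 14 keratins 7 rose and the other 7 were not called, with KRT20 at 1.60 ± 0.36 and KRT80 at 0.19 ± 0.05 (log2 fold change, SE, n = 4 per group), though KRT81 and KRT86 can share reads. KRT20 was at only 0.245 to 0.731 CPM after DMSO recovery, so its fold rests on few counts. Its call was lost in either length-gap class and without the 6 libraries with COL1A2 above 1 CPM. Of 10 genes of laminin-332 and the hemidesmosome, which anchor epithelial cells to the basement membrane, 7 rose, including LAMB3 (0.25 ± 0.04) and the integrin gene ITGB4 (0.18 ± 0.03), and DST fell (-0.16 ± 0.04). Of 9 ligands of the EGF receptor family 4 rose, among them EGF (1.54 ± 0.40), HBEGF (0.36 ± 0.10) and EREG (0.12 ± 0.03), and of 7 subunits of the transcription factor AP-1 5 rose, with FOSL2 at 0.29 ± 0.05 and FOSL1 at 0.21 ± 0.04. FOS, FOSB, FOSL1, JUN and JUNB are also in the immediate early list, so the AP-1 result is not separate from the result for that list. The camera adjusted p with an estimated correlation was 0.00206 for keratins, 0.00116 for laminin-332 genes, 0.00307 for the ligands and 0.00134 for AP-1. Annexins (3 of 10 up, ANXA1 0.15 ± 0.03) and S100 genes (3 of 9 up, S100A14 0.33 ± 0.05) passed only with the preset correlation (adjusted p = 0.000663 and 0.00376, and adjusted p = 0.0700 and 0.137 with an estimated correlation).

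The hnRNP list was lower than at 0 h after UNC0642 recovery, and the list of HMG genes, which encode chromatin proteins, in both recoveries. Of 19 hnRNP genes, which bind nascent transcripts, 15 fell and 1 rose after DMSO recovery and 18 fell after UNC0642 recovery, with HNRNPR at -0.44 ± 0.03 and -0.42 ± 0.03, and adjusted p = 0.0558 and 0.0187 with an estimated correlation, which ends the call after DMSO recovery (adjusted p = 2.27e-08 with the preset one). Of 10 HMG genes 5 fell in each, with HMGN2 at -0.56 ± 0.02 and -0.58 ± 0.02 (adjusted p = 0.00715 and 0.00178 with an estimated correlation). Between UNC0642 and DMSO recovery 4 hnRNP genes and 1 HMG gene (HMGA1) fell. Both lists were called as lower with the preset correlation (camera adjusted p = 0.00278 and 0.0314), and neither with an estimated one (adjusted p = 0.176 and 0.0731). Against 0 h, keratins had 8 up and 2 down after DMSO recovery and 11 up after UNC0642 recovery, laminin-332 genes 5 up and 2 down, then 7 up and 2 down, and AP-1 subunits 5 down, then 3 up and 1 down. The ligands had 1 up and 1 down, then 5 up, annexins 2 up and 3 down, then 2 up and 1 down, and S100 genes 5 up and 1 down, then 6 up and 1 down.

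A hypothesis was that zinc-finger genes lower after UNC0642 lie in runs, since many human zinc-finger genes stand in clusters. In the RefSeq gene order (assembly GRCh38, used only for neighbourhood), 52 of 369 consecutive pairs of tested zinc-finger genes fell together. The mean was 35.9 and the highest value 48 in 10000 shuffles of the calls within chromosomes. No shuffle reached the observed count, and p from the shuffles was 0.0001, the smallest they can give. Neighbouring zinc-finger genes resemble each other, so shared reads may give such runs: among the 118 with whole counts 7 pairs fell together against a mean of 5.20 (share 0.211), which leaves this open. A second hypothesis, that other genes beside the fallen zinc-finger genes are lower too, was not borne out, because the 29 such genes had a median log2 fold change of -0.00 and a share of 0.399 of matched lists had a median as low.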
